A study of Homo sapiens with 9 samples.

How the data were processed

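Precision run-on sequencing (PRO-seq) was carried out on MEL624, a human melanoma cell line. PRO-seq maps RNA polymerases that are engaged in transcription by letting permeabilized cells add a labelled nucleotide to their nascent RNA. The 9 libraries came from 3 groups of 3 biological replicates: control cells carrying a random guide RNA, and 2 clones in which PCIF1 had been knocked out. PCIF1 is the methyltransferase that makes N6,2'-O-dimethyladenosine from a cap-adjacent adenosine. Per the labels' protocols, 10000000 cells were permeabilized. The design text gives 1000000 cells per library, a spike-in of 40000 Drosophila cells, paired reads of 42 nt and an average of 50000000 mappable reads per library.

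The authors deposited a table with 1 mean per group, not a value per library. Per the file header, each value is the mean of normalized counts over the replicates of a group divided by gene length in kb, so it is a signal per kb that the authors had already scaled and averaged. The submitters' processing notes name cutadapt 1.14, Bowtie 1.2.2, featureCounts and DESeq2 with the builds hg38, dm3 and GRCh38.p12, with no role or order. The counted feature, the strand setting, and whether the scaling used the spike-in are not given in the sources used here. The table has 58336 rows. Its header has 6 names and its rows have 5 cells, and the cell for the gene symbol is the one taken to be missing, because the cell after the identifier equals the merged exon length in GENCODE release 44 for 64.4% of the 57754 identifiers found in that release and lies within 5% of it for 83.1%. Those lengths are those of exons, with a median of 0.154 of the gene span for protein-coding genes. Reads of introns may therefore not enter the values. Values are rounded to 0.01, and 23533 rows are 0 in all 3 groups. Symbols, positions (GRCh38) and annotated start bases come from GENCODE release 44, and 582 identifiers had no match.

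The design fixed before the data were examined assumed a value per library and planned moderated tests with adjusted p-values. With 1 mean per group no standard deviation, test or p-value can be had, and no gene is called changed. The deposited values were multiplied by gene length in kb to give a mean normalized count per gene. The log2 ratio of 2 groups was taken after adding a pseudocount of 1, so it understates the ratio of genes with low counts. Genes with a mean count of at least 10 over the 3 groups were compared (17149 genes, of which 12525 are protein-coding), and those with a log2 ratio of at least 1 in size are described as at least 2-fold higher or lower. The planned floor of 10 had been written for the deposited value itself; the scale per kb was run as an alternative. In the text no ratio of a single gene is given where a group is listed at 0, except for ARHGAP20 in clone 2.

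In place of replicate error, the spread of the log2 ratio of clone 2 to clone 1 over genes of like count is used as a yardstick. Its central 95% ran from -1.01 to 1.05 for 5232 genes with counts from 10 to 50, from -0.50 to 0.63 for 6631 genes from 50 to 200, from -0.35 to 0.53 for 4817 genes from 200 to 1000 and from -0.38 to 0.58 for 469 genes above that. It holds real differences between the clones and is not an error of replicates. The depth of single libraries is not known. The summed normalized counts were 3760730 in control, 3759168 in clone 1 and 3823178 in clone 2, which the authors' scaling sets and which are no measure of depth.

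The planned rule for named genes was applied by size alone, without its p-values and its criterion of no overlap between replicates. It took PCIF1; per clone the 8 highest and 8 lowest log2 ratios among genes with a mean count of at least 50; the 10 highest and 10 lowest of the genes at least 2-fold off in both clones, by the smaller ratio; the 5 highest and 5 lowest of clone 2 against clone 1; and in each list the 4 members with the largest mean ratio. Identifiers without a symbol were counted and not named (15 among the genes at least 2-fold off in clone 1 at that floor, 31 in clone 2). Not all genes that this rule takes are reported here. Genes named outside this rule were chosen after their values were seen and are said to be so. Of the 25 gene lists fixed before the data were examined, 24 had at least 5 compared members (blood and endothelial markers had 2). Each list's median was set against 10000 random lists matched on mean count in 20 bins. Such a percentile describes these 3 means and is no test across replicates.

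The clones share the control. A simulation of 100 sets of 3 unchanged groups, with noise drawn from the spread between the clones, gave the correlation and overlap that a shared control brings by chance; real differences between the clones are part of that noise, and the controls could not be split. Medians over overlapping windows of 50 neighbouring genes were set against 10000 random draws of 50 genes. A least-squares segmentation of the log2 ratio along each chromosome was added after the data were seen. Segments of at least 20 genes with a median of at least 0.25 in size are called broad. For its penalty 5 values were tried, and the segments of the real data were seen under each before the choice was made. An interim value of 6 was used before the simulated results were tabulated. The value was then chosen by a rule on simulated data alone: of the penalties with at most 1 segment in 20 random gene orders, the one that recovered most planted segments, or the strictest of those within 2 percentage points of it. It was 5, which recovered 79 of 80 segments of 80 genes shifted by 0.58 and 33 of 40 shifted by 0.42, with 0 segments in 20 random orders of 17004 genes over both clones. The other 4 penalties are given as alternatives. Tested on simulated counts of 17004 genes for clone 1 against control, the 2-fold criterion took 100% of 50 genes raised 3-fold, 98% of 50 lowered 3-fold, 2% of 50 raised 1.5-fold and 0.0417% of 16804 unaltered genes, with counting noise only.

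Alternatives were median-of-ratios rescaling, quantile normalization, pseudocounts of 0.5 and 5, no filter and a floor of 50, and, added after the data were seen, values per kb and leaving out genes of shifted segments. Alternatives for gene lists used 2000 random lists each. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.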

Results

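Nascent transcription was measured by PRO-seq in MEL624 melanoma cells with and without PCIF1, the enzyme that methylates a cap-adjacent adenosine of mRNA. The 9 libraries formed 3 groups of 3 biological replicates: control cells and 2 clones without PCIF1, named clone 1 and clone 2 here. The table analysed gave 1 mean per group, so no value below carries a standard deviation, and whether a difference exceeds the spread between replicates could not be tested. Levels are mean normalized counts per gene. Of the genes listed, 29714 were above 0 in control, 30589 in clone 1 and 29956 in clone 2. At least 10 normalized counts were reached by 17095, 17129 and 17017 genes.

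PCIF1 itself (ENSG00000100982; chromosome 20, 45934683 to 45948023, plus strand) was transcribed in all 3 groups. Its mean normalized count was 239.5 in control, 269.6 in clone 1 and 239.3 in clone 2, log2 ratios of 0.17 and -0.00. A small edit of the coding sequence need not alter nascent transcription of the gene, so these values do not check the labels. Among 23 genes fixed beforehand as its neighbours, the medians were -0.07 in clone 1 and -0.13 in clone 2, inside the central 95% of random lists. SLC13A3, a sodium-coupled carboxylate transporter, stood apart at 4.8, 18.8 and 29.6 counts.

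The first comparison asks whether the level of nascent transcription as a whole differed without PCIF1. The median log2 ratio over 17149 genes was -0.00 in clone 1 and -0.00 in clone 2, and 88.1% and 83.0% of genes lay within 1.5-fold of control. The sources do not say whether the values were scaled to the spike-in, so a difference common to all genes may have been removed before deposit.

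In clone 1, 389 genes were at least 2-fold higher than control and 226 at least 2-fold lower. Among genes with a mean count of at least 50, the highest were silent or nearly so in control. MGMT, a DNA repair enzyme for alkylated guanine, was listed at 0 in control and at 113.5 counts in clone 1. The zinc finger gene ZNF677 and the phosphodiesterase gene PDE3B were also listed at 0 in control, with 78.1 and 66.0 counts in clone 1. The homeobox gene MEOX2 had 1.0 counts in control and 166.8 in clone 1, ZNF844 had 3.7 and 256.4, FLRT2 had 2.4 and 102.6, and the host transcript MIR3667HG had 0.3 and 81.1. The lowest at that floor was EMC10, a subunit of the endoplasmic reticulum membrane protein complex, with 130.4 counts in control and 0.9 in clone 1. Genes off in both clones can miss the floor, such as LINC00540, chosen after its values were seen, with 140.6 counts in control and 0 in each clone. The adhesion gene CADM1 went from 202.3 to 3.9 counts, ZNF556 from 69.0 to 2.0, FAM9B from 213.1 to 34.7, the transporter gene ABCC2 from 348.9 to 65.9 and PCDH7 from 274.0 to 58.9. Each of these ratios lies outside the spread between the clones at its count, which follows from their choice as the most extreme ratios. Low genes made up much of the total: with a floor of 50 counts, 119 genes were at least 2-fold higher and 51 lower.

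Clone 2 differed from control at more genes, with 572 at least 2-fold higher and 325 at least 2-fold lower (213 and 80 with the floor of 50). MGMT, ZNF677, PDE3B, MEOX2, ZNF844 and MIR3667HG were again among the highest, at 133.0, 92.7, 87.0, 164.8, 363.3 and 92.7 counts. CAVIN2, which encodes a coat protein of caveolae, was listed at 0 in control and at 192.6 counts in clone 2, against 15.7 in clone 1. CAVIN2 lies in a segment of chromosome 2 that was higher in both clones as a whole, and MGMT in a segment of chromosome 10 that was higher in clone 2. FLRT2 lies in a run of 6 genes on chromosome 14 that was higher in both clones. With the floor of 50, the lowest genes included CADM1 at 23.5 counts and the kinase gene FAM20C with 117.9 counts in control and 14.0 in clone 2. The laminin gene LAMB3 had 199.7 and 30.6, and the circadian transcription factor gene NPAS2 had 399.5 and 94.3. LAMB3 was at 181.1 counts in clone 1. Of the genes at least 2-fold off, 63.3% were higher in clone 1 and 63.8% in clone 2. These shares were 70.0% and 72.7% with the floor of 50, 53.2% and 51.2% on the scale per kb, and 49.4% and 49.5% with no filter on low counts. The filter takes the mean of control and 2 clones, so it favours genes higher in both clones over genes lower in both.

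The clones had 284 genes at least 2-fold higher in common and 101 at least 2-fold lower. Both clones are set against the same control mean, so a deviation of control alone would also place a gene here. Beyond the genes above, SH3GL2, an endocytosis gene, had 3.6 counts in control and 62.6 and 94.4 in the clones, and the adhesion receptor gene ADGRF1 had 7.6, 136.9 and 77.0. Lower in both were ABCC2, PCDH7, the F-box gene FBXL7 (115.5, 37.3 and 31.2), the kynureninase gene KYNU (147.1, 53.9 and 53), the muscarinic receptor gene CHRM3 (104.8, 32.1 and 41.1), BOLA1 (487.7, 195.4 and 181.4) and the noncoding RNA LINC00668 (156.2, 38 and 62.8), which lies in a segment of chromosome 18 that was lower as a whole. BOLA1 overlaps the histone gene H2AC21, and reads of overlapping genes may be split between them. On chromosome 18, MOCOS, the molybdenum cofactor sulfurase gene, was 4.26-fold lower in clone 1 and 3.58-fold lower in clone 2, and its neighbour ELP2, an Elongator subunit gene, went from 678.9 counts to 213.2 and 228.2. The adjoining SLC39A6, a zinc transporter gene chosen after its values were seen, had 79.6, 19.1 and 24.1 counts.

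**Figure D1:**
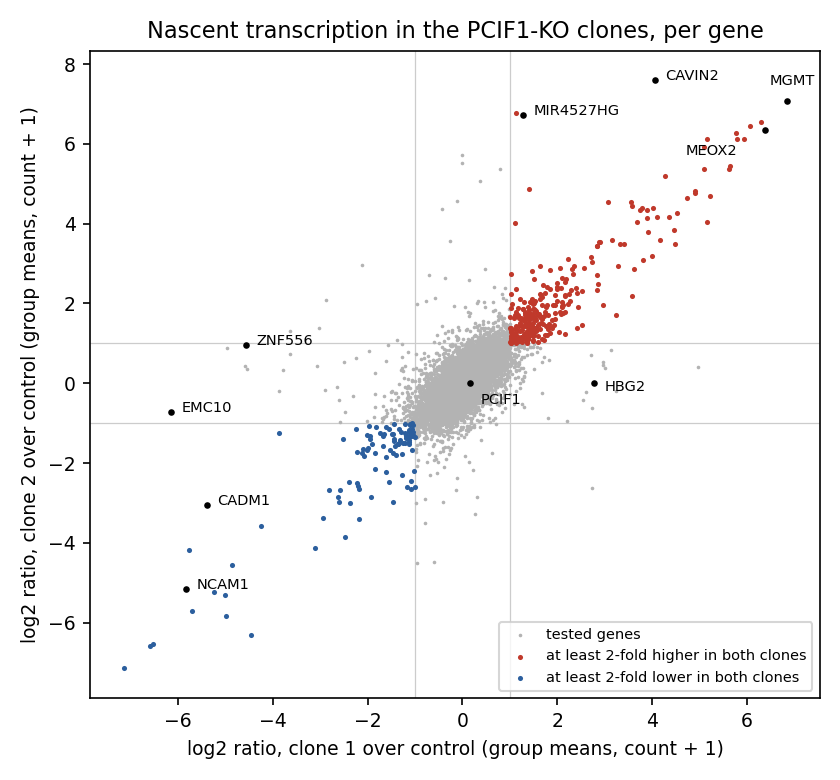
Log2 ratio to control of each of 17149 genes in clone 1 (x axis) and clone 2 (y axis), from group means with a pseudocount of 1. Red points are the 284 genes at least 2-fold higher in both clones, blue points the 101 at least 2-fold lower in both, black points genes named in the text, and grey lines mark 2-fold.

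Across genes, which are not independent replicates, the log2 ratios of the clones had a Pearson correlation of 0.741 and a Spearman correlation of 0.687. Unchanged groups sharing a control gave 0.500 and 0.466 in simulation. The covariance was 0.227, against 0.0820 simulated, a difference of 0.145. The simulation gave on average 65.2 genes higher and 64.1 lower in both clones, with at most 85 and 90. The filter on low counts was not applied to the simulated groups, so their balance of higher and lower genes cannot be set against the observed one. Independent lists of these sizes would share 13 and 4.28. Part of the excess may still come from the shared control, which could not be split. For the mean of the clones against control, 420 genes were at least 2-fold higher and 210 lower.

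Compared directly, clone 2 was at least 2-fold above clone 1 at 180 genes and below it at 160 (40 and 24 with the floor of 50). ZNF556 had 69.0 counts in control, 2.0 in clone 1 and 135.2 in clone 2. MIR4527HG had 0.7, 3.1 and 176.0 counts, FHAD1 had 25.9, 19.8 and 165.4, and EMC10 was at 78.5 in clone 2. In the other direction, the gamma-globin gene HBG2 had 38.6 counts in control, 272.1 in clone 1 and 39.1 in clone 2. OR51B5 (21.6, 181.4 and 28.6) and the pseudogenes OR51A10P (16.3, 133.5 and 22.8) and OR51B8P (14.1, 117.4 and 21.0) overlap the annotated HBG2 gene on chromosome 11, 5253188 to 5505605, minus strand, so these entries may count the same transcription.

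Gene lists fixed beforehand were compared by their medians. By chance about 1.2 of 24 lists of unrelated genes would fall outside the central 95% of random lists in a clone, and 6 did in each. Genes of a list can vary together, which random lists do not allow for, and the clones share the control. The excess over 1.2 is therefore no test. Genes of cholesterol synthesis had the highest median in clone 1, 0.31 (percentile 100) with 16 of 23 members above control, and a median of 0.27 in clone 2 (percentile 99.9) with 18 of 23 above. The lanosterol demethylase gene CYP51A1 had 62.3, 128.6 and 158.6 counts in control, clone 1 and clone 2. It was the single member at least 2-fold off. SC5D (121.9, 211.6 and 235.6), STARD4 (71.0, 131.5 and 123.4) and LSS (98, 140.8 and 157.4) were within 2-fold. Genes of ATF4 and the unfolded protein response had medians of 0.14 and 0.27 (percentiles 99.7 and 100), with 21 and 25 of 31 members above control. The serine synthesis genes PSPH (432.4, 575.6 and 708.8) and PSAT1 (300.6, 389.8 and 456.0) were among them, whereas NUPR1 had 17, 9.5 and 74.7 counts. On the scale per kb the medians of this list were 0.14 and 0.23 and neither was outside the random range.

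Type I interferon response genes had medians of 0.19 in clone 1 (percentile 99.9) and 0.16 in clone 2 (percentile 96.9, inside the range, but outside it under 4 alternatives). For the mean of the clones it was 0.11, inside the range. IFI44L had 25.6, 60.1 and 54.6 counts and HERC5 5.1, 15.4 and 17.5. IRF7 had 17.9, 0.3 and 15.7. Heat shock genes had medians of 0.115 and 0.105, outside the range in clone 1. That call was lost under 4 alternatives: no filter, a floor of 50, the scale per kb, and without genes of shifted segments, which hold HSPE1 and HSPD1. The 56 replication-dependent histone genes had medians of -0.12 (percentile 0.0) and -0.10 (percentile 5.5). Of 8 neural crest and Schwann-like markers, 3 were at least 2-fold lower in clone 1 and 1 in clone 2, with medians of -0.33 (percentile 0.8) and -0.17. The adhesion gene NCAM1 went from 84.3 counts to 0.5 and 1.4, while SOX2 had 34.8, 10.6 and 51.5.

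In clone 2, 4 lists lay below their random lists: markers of the dedifferentiated melanoma state (median -0.26, 21 of 25 members not above control), MAPK pathway output (-0.25), immediate early genes (-0.17) and proliferation (-0.16). In clone 1 their medians were -0.05, -0.11, -0.07 and -0.03, inside the range, although the immediate early genes lay outside it with no filter and per kb (-0.10 in each). For the mean of the clones all 4 lists lay outside it, with medians of -0.18, -0.21, -0.13 and -0.11. The difference between the clones was not tested. TGFBI, a matrix protein gene, had 149.0, 91.9 and 69.7 counts, the phosphatase gene DUSP4 2050.6, 1493.4 and 1290.2, KLF2 734.6, 402.8 and 392.6, and E2F8 71.1, 58.4 and 20.1.

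None of 38 genes of the cap and m6A or m6Am machinery, 40 of polymerase pausing and elongation, 80 ribosomal proteins, 44 translation factors or 33 of ribosome biogenesis was at least 2-fold off in either clone, and their medians ran from -0.06 to 0.00. METTL4, a methyltransferase gene of the first list with 347, 228.2 and 220.6 counts, lies in the segment of chromosome 18 that was lower as a whole. The ribosome biogenesis genes NOP58 (1165.9, 2145.7 and 2075.6) and NOP56 (1916.1, 1193.3 and 1220.5) lie in shifted segments of chromosomes 2 and 20. The other lists were inside the range in both clones: the melanocyte lineage (-0.08 and 0.08), antigen presentation (0.02 and -0.04), p53 targets (0.01 and 0.08), hypoxia and glycolysis (0.01 and 0.03), NF-kB targets (0.15 and 0.13), fibroblast markers (0.10 and 0.26), epithelial markers (-0.27 and -0.33) and cancer-testis antigens (0.17 and -0.13). For the mean of the clones, 3 of these lists lay outside the range: fibroblast markers (0.41, 8 genes), NF-kB targets (0.21, 18 genes) and epithelial markers (-0.42, 5 genes). Single members still differed. The melanosome gene PMEL, which overlaps CDK2, had 48.4, 21.3 and 23.8 counts, EDNRB 6.6, 18.9 and 20.4, CD74 86.7, 35.3 and 24.5, the cancer-testis gene PRAME 94.9, 201.6 and 198.7, ICAM1 52.6, 176.8 and 84.2, and GDF15 205.6, 231.3 and 694.1.

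**Figure D2:**
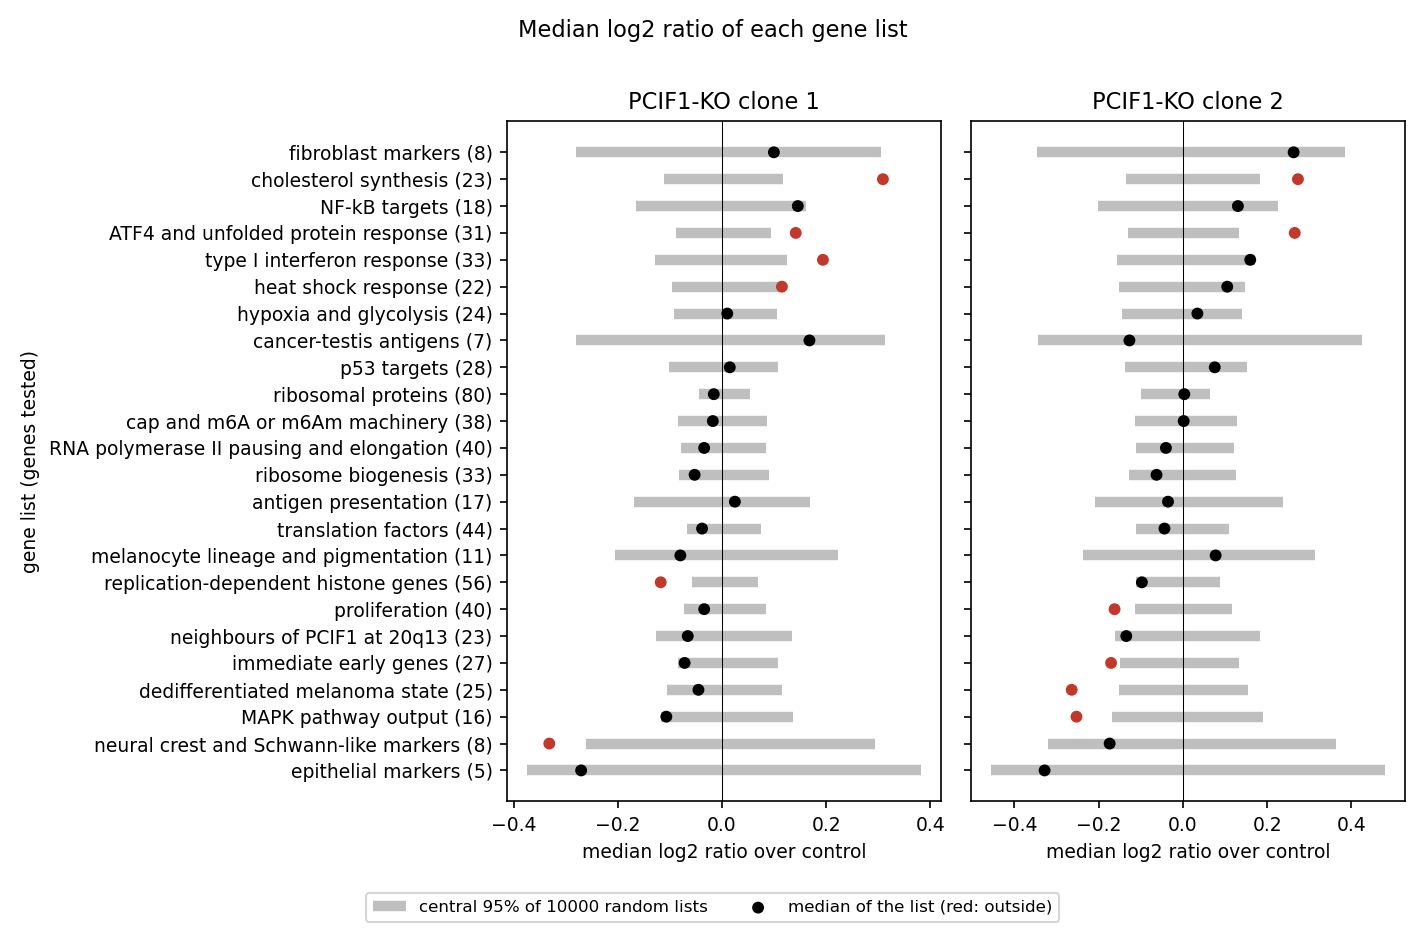
Median log2 ratio to control of each of 24 gene lists in clone 1 (left) and clone 2 (right), with the number of genes compared in brackets. Grey bars span the central 95% of 10000 random lists matched on mean count, and red points are the 6 medians per clone that lie outside their bar.

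Position along the genome was examined because a region present in another number of copies would move neighbouring genes together. Of 648 windows of 50 genes, 5.40% in clone 1 and 9.72% in clone 2 had medians beyond every one of 10000 random draws. Successive windows overlapped, so a shifted region can be counted more than once. Broad segments called in both clones lay on chromosomes 2, 18 and 20 and in gene clusters of chromosomes 5 and 19. On chromosome 2, 82 genes from 190189735 to 203014798 (HIBCH to WDR12) had medians of 0.64 in clone 1 and 0.58 in clone 2, and 85 genes from 230984368 to 242078722 had medians of 0.50 and 0.47. On chromosome 18, 93 genes from 158383 to 14974215 had medians of -0.51 and -0.60. On chromosome 20, 71 genes from 270863 to 6040053 had medians of -0.67 and -0.65, and in clone 1 the segment reached 10673999. Clone 2 alone had segments of chromosome 3 (470 genes, 3126933 to 94063389, median 0.41 against 0.01 in clone 1) and of chromosome 10, where 155 genes from 42336101 to 75401764 had a median of 0.63 (0.07 in clone 1) and 324 genes from 75401519 to 133561220 a median of 0.32 (-0.02 in clone 1). A segment was called at each of these places under all 5 penalties tried, with ends that differed. In clone 1 the second of chromosome 2 was called as 2 segments at the 2 smallest penalties, and the largest penalty joined the 2 of chromosome 10.

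Of the genes with at least 50 counts, 2.42% lay in broad segments of clone 1 and 8.14% in those of clone 2, and these held 17.6% and 28.7% of the genes at least 2-fold off. Segments were called on these same ratios, so a higher share inside them follows from how they were chosen. The clusters called in both clones were zinc finger genes on chromosome 19 (35 genes from 19710472 to 22091480 in clone 1, medians 0.56 and 0.35), which clone 2 lost at the 3 largest penalties, and protocadherin genes on chromosome 5 (39 genes from 140794852 to 141512977 in clone 1, medians 0.92 and 0.60), which clone 2 lost at the 2 largest. Protocadherin genes of the alpha and gamma clusters share exons, and their values are uncertain. A segment of chromosome 5 from SEMA6A to ADAMTS19 (medians 0.28 and 0.28) was called in clone 1 at the smallest penalty alone. Runs under 20 genes were called at 3 places. On chromosome 14, 6 genes from 82642600 to 86161539 had medians of 1.60 and 2.26. On chromosome 18, 6 genes from 36108531 to 36274599, which hold MOCOS and ELP2, had medians of -2.04 and -1.72, and in clone 1 the run had 1 more gene. On chromosome 11, 11 genes from 5253188 to 5678434, which hold HBG2, had medians of 2.79 and 0.02 and were called in clone 1 alone.

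**Figure D3:**
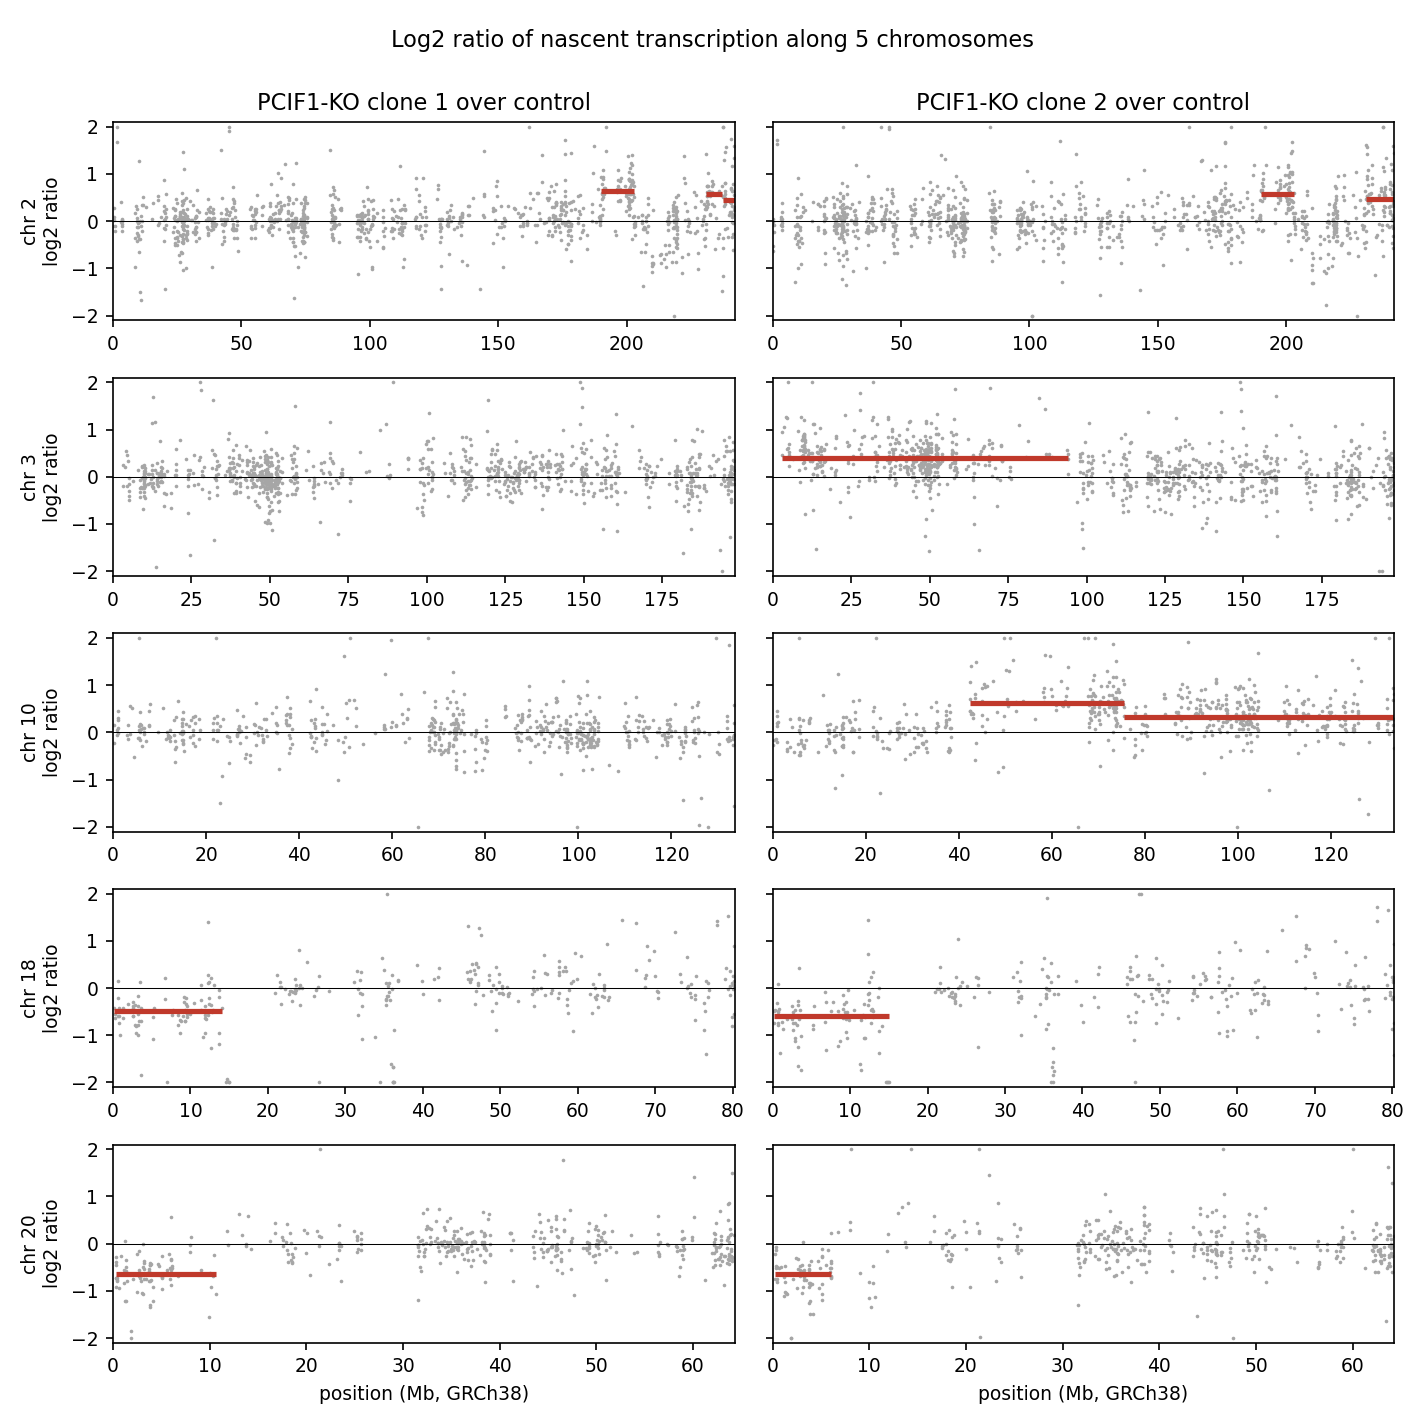
Log2 ratio to control of each gene (grey points, values beyond 2 in size drawn at 2) against its start position in Mb on 5 chromosomes, for clone 1 (left) and clone 2 (right). Red lines span the broad segments at their median, such as 0.41 on chromosome 3 in clone 2.

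Because PCIF1 acts on a cap-adjacent adenosine, protein-coding genes were grouped by the first base of their annotated canonical transcript. The 5876 genes starting with A had a median 0.02 above the other genes in clone 1 and 0.03 above them in clone 2 on the log2 scale (percentiles 99.7 and 100 of 1000 random lists), a fold of 1.02 for the mean of the clones. The 5222 genes starting with G lay below the other genes by like amounts (differences of -0.02 and -0.04, percentiles 0.7 and 0), and the 1379 starting with C differed from the others by -0.0027 and 0.0078 (percentiles 27.5 and 80.7). In clone 2, 3.35% of genes starting with A were at least 2-fold higher and 1.65% lower, against 2.32% and 1.28% of genes starting with G. The annotated base may differ from the base at which transcription began in these cells. These random lists were matched on mean count alone. Whether GC content, length or position of the genes accounts for differences of this size was not tested, so they cannot be assigned to PCIF1.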

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

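The tests of this part were chosen after the results were seen. Genes at least 2-fold off in opposite directions in the clones numbered 6, against 385 in the same direction. The difference between the clones was not tested, since each group has 1 mean, and it rests on group means rather than on every sample. TERT, the telomerase reverse transcriptase gene, had 26.2 counts in control, 1.2 in clone 1 and 65.9 in clone 2, log2 ratios of -3.63 and 1.30. ZNF525 had log2 ratios of -2.89 and 2.09 and ZNF560 of -2.12 and 2.96. ARHGAP20 had 2.74 in clone 1 and -2.63 in clone 2, where it was listed at 0, so the second value depends on the pseudocount. LINC00601 had -1.38 and 1.10. The remaining entry has no symbol. The 29 mitochondrial genes had medians of -0.23 in clone 1 and 0.28 in clone 2, with 24 below control in the first and 23 above it in the second. They made up 2.81% of normalized counts in control, 2.18% in clone 1 and 3.66% in clone 2.

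Of 33 genes with at least 50 counts in a group (on) and at most 2 in another (off), 9 were on in one clone and off in the other, among them TERT, ZNF556, EMC10 and ZNF718. These 9 were chosen by that criterion, so their count decides nothing about loss of PCIF1 as a cause. In 15 of the 33, both clones were on and control off, or both off and control on, as with MGMT, MEOX2 and RELN (on in the clones) and NCAM1, COBL and FAM111B (off in the clones). There, loss of PCIF1 and another history of the control population cannot be told apart, because a single control group stands against both clones. In 26 of the 33 neither nearest compared gene was at least 2-fold off in the same direction, and in 7, which include the adjacent PDE3B and CYP2R1, one was. A deletion or gain cannot be told apart from other causes in either set: the nearest compared gene lay 566 kb from COBL, for example, and overlapping genes were not taken as neighbours.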

How the results depend on the processing

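No paired analysis was possible because the table gives 1 mean per group. For the same reason the planned replicate block, fits of the compared groups alone, sample weights, robust variance prior, edgeR and DESeq2 fits, leaving out of each library, and set tests with an estimated correlation or by fry were not run. No log2 ratio of a named gene at least 2-fold off, and no list median outside the random range, turned its sign. The balance of higher and lower genes did turn with no filter, in each comparison, and per kb for clone 2 against clone 1. Of 1892 values of named genes other than PCIF1, 1796 moved by less than 1 robust SD between the clones and 96 by more, and of 370 list medians 6 fell inside the random range and 10 moved outside it. The 1796 include 256 values with no filter, 198 with a floor of 50 and 222 without genes of shifted segments. Those settings only choose which genes are kept, so the ratio of a single gene could not move under them. Median-of-ratios rescaling and quantile normalization moved no count by over 1.5 times.

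Counts of genes at least 2-fold off depended on the filter, as its construction adds or removes genes of low counts, where the spread is widest. The filter is also uneven in direction. It takes the mean of control and 2 clones, so a gene silent in control passes more readily than one silent in both clones. How far this sets the balance of higher and lower genes was not tested. With no filter the higher and lower genes were 1403 and 1435 in clone 1, 1792 and 1831 in clone 2, 1212 and 1245 for the mean of the clones, 1054 and 1122 for clone 2 against clone 1, and 710 and 730 in both clones, with a correlation of 0.660. With a floor of 50 they were 119 and 51, 213 and 80, 139 and 52, 40 and 24, and 94 and 22. A pseudocount of 5 left 212 genes lower in clone 2 and 89 for clone 2 below clone 1. Values per kb, chosen after the data were seen, gave 344 lower in clone 1, 502 lower in clone 2, 273 and 327 for clone 2 against clone 1, and a correlation of 0.677; the cause was not tested.

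The heat shock list in clone 1 fell inside the random range with no filter and with a floor of 50 (median 0.115 in each), per kb (0.115) and without genes of shifted segments (0.0733). Genes of ATF4 and the unfolded protein response did so per kb alone (0.143 and 0.231). The 10 that moved outside were interferon genes in clone 2 with quantile normalization (0.14), no filter (0.16), a floor of 50 (0.23) and per kb (0.23), immediate early genes in clone 1 with no filter (-0.10) and per kb (-0.10), NF-kB targets per kb (0.23 and 0.39), histone genes in clone 2 per kb (-0.10) and fibroblast markers in clone 1 without genes of shifted segments (0.38). Windows beyond all random draws made up 3.48% (clone 1) and 5.50% (clone 2) at 25 genes and 11.1% in clone 1 at 100 genes; the cause was not tested. The segmentation and its penalties were chosen after the data were seen, and the number of broad segments stayed within 1.5 times under all 5.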

Other observations

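Genes named in this part other than H1-1 lie outside the rule for named genes and were chosen after their values were seen. The on and off pattern took in genes of diverse known roles. RELN, the gene of the extracellular protein reelin, had 1.8 counts in control and 72.6 and 67.6 in the clones, and the vitamin D hydroxylase gene CYP2R1 had 0.4, 67.6 and 58.7. COBL, an actin nucleator gene, and FAM111B were listed at 0 in both clones, against 95.4 and 51.1 counts in control. PRKG1, a cyclic GMP-dependent kinase gene, had 1.0, 38.0 and 72.9 counts. The linker histone gene H1-1 had 59.8, 30.2 and 1.7. By class of transcript, 118 small nucleolar RNAs had medians of 0.07 in clone 1 and 0.45 in clone 2. Classes below their random lists in clone 2 were 341 processed pseudogenes (-0.02 and -0.23), 57 miscellaneous RNAs (-0.17 and -0.23) and 244 genes of the class TEC (-0.06 and -0.15). Above them were 3205 lncRNAs (0.02 and 0.03) and 44 transcribed unitary pseudogenes (0.07 and 0.17).

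The broad segments are a pattern for which the test of GC content, length and expression level was written before its result was seen, and the other tests of this part after. The real order of the genes gave 17 segments, where a place called in both clones counts once for each, and the highest of 20 random orders gave 0. The penalty had been chosen to give at most 1 segment in 20 random orders, so a value near 0 there was set beforehand. The 17 of the real order was not set by that choice. The median of genes matched on GC content, length and expression level was then taken off. After that 16 of the 17 kept a median of at least 0.25 in size, which argues against these properties as the cause in those 16. The exception was the segment of chromosome 5 from SEMA6A to ADAMTS19, which fell from 0.28 to 0.22. A different number of DNA copies is a candidate explanation for chromosomes 2, 3, 10, 18 and 20, and no DNA was measured. There 11 of 12 segments, counted per clone, had at least 80% of genes on one side. They also had a shift of at least 0.25 among genes of low, middle and high expression alike. The other, in clone 1 from 237574322 to 242078722 on chromosome 2, had a median of 0.19 among its genes of middle expression. Segments were called on these same ratios, so such even shifts largely follow from the call. The criterion therefore cannot decide for a copy difference. In the segment of chromosome 5 from SEMA6A to ADAMTS19 the 12 most highly expressed genes had a median of 0.0719 (bootstrap interval over genes -0.06 to 0.21). Its genes of low and middle expression had medians of 0.90 and 0.50. These values argue against an even shift of at least 0.25 over that segment. Genes are not replicates, and a smaller copy difference, or one of part of the segment, cannot be excluded. The 4 segments of the zinc finger and protocadherin clusters all met the criterion too. In them a copy difference cannot be told apart from regulation or shared reads of gene families. Over the segments of chromosomes 3 and 10 the median of clone 1 was at most 0.07 in size (0.0740), so the shift was not common to the clones without PCIF1. These segments were chosen as called in clone 2 alone, so a low median in clone 1 decides nothing further about loss of PCIF1 as a cause.

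The order of rows in the table is itself structured. The first 182 rows were all lower in both clones than in control, and 322 rows from row 187 to row 508 were all higher in both; in random orders of the compared rows the longest such run was 18. An order unrelated to the values is therefore argued against. A candidate explanation is a sort by an outcome of the authors' own comparison, which the labels do not describe and which was not tested. Of these rows, 81 and 174 were at least 2-fold off in both clones, and 38.1% of the 160 and 26.9% of the 316 that were compared lay in broad segments, against 8.20% of all compared genes. Segments and runs were both picked by the direction of these same ratios, so a higher share follows from how they were chosen.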
